A study of Mus musculus with 4 samples.

How the data were processed

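Posterior tissue of mouse embryos at 5 to 6 somites was compared between Cdx2+/- Cdx4-/- mutants and wildtype. The tissue was cut at the last somite boundary and pooled from 10 embryos per genotype, per the labels. Both RNAs were hybridised together to each of 4 Agilent whole mouse genome arrays of 2 colours. The labels name the arrays as 2 replicates, each with a dye swap. All 4 arrays lie on 1 slide, so no slide or scan could be tested as a batch.

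The scanner files were made with Agilent Feature Extraction 9.5.3, per the submitters' processing notes. Per the file headers they give an intensity for each spot, as the mean signal and the median local background of Cy3 and Cy5, together with background-subtracted and dye-normalised intensities. The deposited scanner files also give a log10 ratio of Cy5 over Cy3 and a p-value for that log ratio, per the file headers. The authors' series table holds log10 values. With a tolerance of 1e-05, these equalled the scanner log ratio for 100% of features on the 2 arrays titled without a dye swap. They equalled its negative for 100% of features on the 2 dye swaps. The scale of that table is therefore log10 and its direction is mutant over wildtype by the labels, with no further centring and a median of 0 in each column.

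The spot intensities were background-corrected in limma 3.58.1 (R 4.3.3) by normexp with an offset of 50, and normalised within each array by loess with control spots at weight 0. Control spots and outlier spots (103 to 167 per array) were then left out, and saturated spots (0 to 7 per channel) were kept. Spots of 1 probe were averaged. A probe was tested if it was well above background on all 4 arrays in the channel of at least 1 genotype. Each gene was represented by its brightest tested probe. Of the 41174 probes, 23374 were named through a RefSeq accession in a GRCm38.p6 gene table, 6733 already had a current symbol, 2919 were renamed from an older symbol and 8148 kept the name in the file. Positions are those of the scanner files, on mm8, and no genome sequence was used here. Array number limits the precision of every value.

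As fixed before the data were examined, each dye-swap pair was averaged by its labelled replicate, and the 2 values were fitted with lmFit and eBayes, with Benjamini-Hochberg adjustment over probes and a threshold of 0.05. This is called the fit as labelled. The targeted genes and the correlations between arrays then ran against the labels of 2 arrays. A further fit, called the aligned fit, was therefore added after the data were seen, with the 4 arrays turned to run the same way. In it the values set the genotype of the channels of 2 arrays against their labels, and the filter on dim probes followed those channels. The aligned ratio has the sign given by the labels of the arrays labelled replicate 1 and replicate 2 dye swap. By the labels of the other 2 arrays it has the opposite sign.

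Aligned arrays can be paired in 3 ways and all 3 were fitted. Array 1 is labelled replicate 1, array 2 its dye swap, array 3 labelled replicate 2 and array 4 its dye swap. Of the exchanges of 2 labels, those of arrays 2 and 3 or of arrays 1 and 4 make all 4 arrays run the same way, and both pair array 1 with 3 and array 2 with 4. These dye-balanced pairs are called the exchange pairing. If instead the replicate numbers are right and the dyes are wrong, arrays 1 and 2 form 1 replicate and arrays 3 and 4 the other. This is called the labelled-number pairing, in which dye bias stays in the spread. In the exchange pairing limma estimated an infinite prior degrees of freedom, so that nearly all genes share a standard error of 0.05 (log2). If the labelled numbers are right, that error leaves out the spread between replicates and its calls are too many. The standard errors and adjusted p-values printed for named genes come from the labelled-number pairing, the stricter of the 3, and a gene is said to have changed where it passed in it and in the exchange pairing. Nothing in the labels says that the replicates came from separate pools, so p-values measure only the spread between these hybridisations, which may be technical. That spread is also largely pooled over genes. In the labelled-number pairing, limma set 17.2 prior degrees of freedom beside the 1 residual degree of freedom of each gene. The printed standard errors are therefore moderated values and not the spread of a gene's own 2 replicates alone.

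Gene lists fixed before the data were examined (26 lists) were tested with camera at a preset correlation of 0.01, and each list's median was ranked among 10000 random lists matched on mean signal. Camera was also run with a correlation estimated for each list. That test rests on 1 residual degree of freedom, so it has little power to call any list. The named genes are Cdx1, Cdx2 and Cdx4, the 12 largest increases and 12 largest decreases with the same sign on all 4 arrays and a gene symbol that is not an accession, clone, Rik or Gm name, and up to 4 passing members of each list with the largest change, or 2 with the smallest p where none passed. The rule was applied to the exchange pairing. Adjusted p-values of lists in the aligned fit are also those of the exchange pairing, even where they follow counts of the labelled-number pairing. In 101 of the 5101 genes with 2 or more tested probes, called probes went opposite ways. Wtap and Gcnt1 are among these 101 and are reported with that limit. Separately, some other genes are not reported here.

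The fit was tested on simulated data of 21800 probes for this comparison, with the spread of the exchange pairing. It recovered 64% of the 50 probes changed by 0.2 (log2) and 100% of those changed by 0.5, 1 or 2, with 6 false calls among 188. The simulated probes were independent and shared 1 variance, as the fit assumes. The result therefore checks how the fit runs and does not measure the share of false calls in these data. The alternatives tried covered background correction, normalisation, filters, outlier spots, the series table, dye orientations, single replicates, the error model, the threshold and the rule for genes. Those added after the data were seen were the aligned fit with its alternatives, the pairings, the 2 arrays of each labelled replicate alone in the fit as labelled, and subsets of 2 aligned arrays, named by array number because the dye of the mutant is open. Figures were drawn with matplotlib 3.10.9.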

Results

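The data were 4 hybridisations of posterior embryonic tissue of Cdx2+/- Cdx4-/- mutants against wildtype at 5 to 6 somites. The design asks which genes differ between the genotypes in the tissue that extends the body axis. Between 50.6% and 56.4% of spots were well above background in Cy3, and between 58.9% and 64.9% in Cy5.

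The targeted genes were examined first on every array. Cdx4, a caudal homeobox gene whose probe lies on chromosome X at 99532694 to 99532753 (mm8), had log2 Cy5 over Cy3 ratios of -2.59 and -2.11 on the arrays labelled replicate 1 and replicate 1 dye swap. Its ratios were 2.82 and 2.42 on the arrays labelled replicate 2 and replicate 2 dye swap. By the labels, Cdx4 was thus lower in the mutant on the arrays labelled replicate 1 and replicate 2 dye swap, and higher in the mutant on the other 2. Cdx2 (chromosome 5, 147611320 to 147611379) followed the same pattern, with ratios of -0.77, -0.50, 0.45 and 0.45 in the same order. Cdx1 (chromosome 18, 61145778 to 61145837) ran the other way, with 0.07, 0.32, -0.57 and -0.62. Whether the Cdx4 and Cdx2 probes lie in the removed parts of the genes is not given in the sources used here, so they check the labels only as far as the transcripts are lost.

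**Figure D1:**
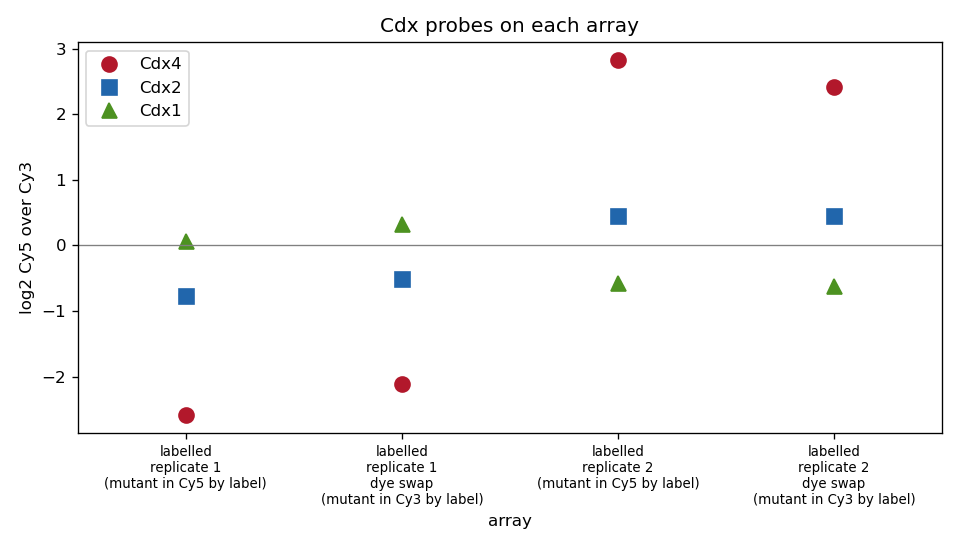
Log2 Cy5 over Cy3 of the Cdx4, Cdx2 and Cdx1 probes (vertical axis) on the 4 arrays (horizontal axis, with the dye of the mutant by the labels), 1 point per array. Cdx4 lies at -2.59 and -2.11 on the first pair of arrays and at 2.82 and 2.42 on the other, although the labels swap the dyes within each pair.

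The whole arrays showed the same conflict. Over 21859 probes, the arrays labelled replicate 1 and replicate 1 dye swap correlated at r = 0.82 in Cy5 over Cy3, and those labelled replicate 2 and replicate 2 dye swap at r = 0.87, although the labels swap their dyes. Arrays with the same labelled orientation correlated at r = -0.43 in both cases. Over all 41174 probes these were -0.36 and -0.38. The correlations are across genes, which are not independent replicates. The direction of the ratios is therefore not settled by the labels, and the authors' series table carries the same conflict.

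Fitted as labelled, the arrays largely cancelled. In limma, 2 genes were called higher and 12 lower of 14444 tested, with 239 at an unadjusted p under 0.05, and 46 probes against 21 were called when the sign of replicate 2 was turned. Of the 14, 5 had the same labelled sign on all 4 arrays. Acss1, 1 of the higher genes, named here after its value was seen, had labelled ratios of 0.51, -0.39, 1.18 and 0.47 on arrays 1 to 4. Cdx4 had the same labelled sign on 2 arrays and the opposite on 2. No gene reached 2-fold in both labelled replicates. Of the gene lists, 1 passed, p53 pathway and apoptosis, with a median log2 ratio of -0.03 (adjusted p = 0.0295, and adjusted p = 0.988 with an estimated correlation). That call ended in 12 of 16 alternatives.

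All further values are aligned ratios, chosen after the data were seen. Their sign is mutant over wildtype by the labels of the arrays labelled replicate 1 and replicate 2 dye swap. By the labels of the other 2 arrays every sign turns, higher and lower change places, and Cdx4 would be higher in Cdx4-/- tissue. In the exchange pairing 3208 genes were higher and 2792 lower of 14842 tested, or 2792 higher and 3208 lower with the sign turned. In the labelled-number pairing 436 were higher and 580 lower, or 580 and 436 with the sign turned. The third pairing gave 4310 and 3622, so the number of genes called rests on which labels are wrong. With median centring in place of loess, limma called 0 genes in the exchange pairing, with 29 at an unadjusted p under 0.05, and the median over all genes tested was 0.28. Cy5 over Cy3 then drifted with brightness, to a median log2 ratio of 1.86 among the brightest probes of the array labelled replicate 1 dye swap. By size, 11 genes were at least 2-fold higher and 7 at least 2-fold lower in both pairs. These counts were 76 and 153 with the authors' series table, and 74 and 164 with the scanner's processed signals. The arrays whose labels go with a lower Cdx4 level, used alone as labelled, with the filter on dim probes also set by the labels (14446 genes tested), gave 228 higher and 358 lower genes, and the other 2 arrays as labelled gave 256 and 237. All 405 genes called in both subsets had opposite signs in them.

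In the aligned ratios Cdx4 was 5.60-fold lower (log2 -2.48 ± 0.10, moderated SE, n = 2, adjusted p = 1.56e-11) and Cdx2 was 1.46-fold lower (log2 -0.54 ± 0.10, adjusted p = 0.00186). Cdx1, the third member of the family, was 1.32-fold higher (log2 0.40 ± 0.11, adjusted p = 0.0304). All 3 kept their sign on all 4 arrays, which is no separate support, since the arrays were aligned after these ratios had been seen. With median centring in place of loess, the calls of Cdx2 and Cdx4 in the exchange pairing ended with those of all named genes, at log2 ratios of -0.11 and -2.24 against 0.28 over all genes. With only arrays 2 and 4, Cdx2 was at -0.48 and its call ended (adjusted p = 0.0673). All these directions turn with the labels of the other 2 arrays.

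The 24 largest changes passed in both pairings. Among the decreases were Rian, an imprinted non-coding RNA, at log2 -2.47 ± 0.10 on its brightest probe, Afp, the alpha-fetoprotein gene, at -2.04 ± 0.10, and Prl8a2, a prolactin family gene, at -1.41 ± 0.10. Cubn (-1.12), Sparcl1 (-1.08), Rbp4 (-1.07), Dgkk (-1.03), Wtap (-0.99), Gcnt1 (-0.99), Kdr (-0.97) and Aqp8 (-0.94) completed them with Cdx4. Another probe of Wtap and of Gcnt1 went the opposite way, and the other probe of Rian was at -0.0014 (adjusted p = 0.987 in the exchange pairing). Among the increases were the embryonic globins Hbb-bh1 (1.35 ± 0.10) and Hba-x (1.12 ± 0.11), the collagen gene Col26a1 (1.21 ± 0.09) and Fam183b (1.15). The procollagen peptidase gene Adamts2 (1.12) was also among them, with its other probes at only 0.30 and 0.38. So was Etnk2 (1.08), whose other probe was at -0.027 (adjusted p = 0.725 in the exchange pairing). The other 6 were the defensin genes Defcr-rs2 (1.42), Defcr-rs10 (1.34), Defa31 (1.19), Defa20 (1.16), Defa3 (1.14) and Defcr4 (1.02). These near-identical paralogs can share signal between probes, so which of them changed is uncertain.

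Markers of extraembryonic visceral endoderm, the outer epithelium of the yolk sac, were lower in all 13 measured genes in both pairings. Their median log2 ratio was -0.71, below all 10000 random lists (percentile 0, camera adjusted p = 4.26e-48, and adjusted p = 0.643 with an estimated correlation). The count was also 13 adjusted over the list alone. Afp, Cubn, Rbp4 and Spp2 (-0.93 ± 0.11) fell most. This marker shift was present in the same tissue as every list below, and whether it bears on their values was not tested.

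Endothelial markers were lower in 10 and higher in 2 of 15 genes in the exchange pairing, and lower in 7 and higher in 1 in the labelled-number pairing (median -0.23, adjusted p = 1.06e-06, and adjusted p = 0.668 with an estimated correlation). Kdr, a VEGF receptor, Etv2 (-0.72 ± 0.09), an early endothelial and blood regulator, Sox7 (-0.48) and Sox18 (-0.43) fell. With median centring the list's median was 0.03 against 0.28 over all genes, and the list still passed as lower than other genes (adjusted p = 0.00365). Primitive erythroid genes went the other way, with 5 of 7 higher and 1 lower, or 3 and 0 in the labelled-number pairing (median 0.28, adjusted p = 1.18e-09, and adjusted p = 0.643 with an estimated correlation). Hbb-bh1, Hba-x and Hbb-y (0.72 ± 0.11) rose, and Hba-a1, at -0.28, did not pass in the labelled-number pairing.

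Presomitic mesoderm and somite genes were higher in 9 of 13 and lower in 0, or 4 and 0 in the labelled-number pairing (median 0.17, adjusted p = 1.07e-06, and adjusted p = 0.643 with an estimated correlation). Meox1 (0.91 ± 0.10) and Tcf15 (0.85 ± 0.10), transcription factors of the somite, and Aldh1a2 (0.47 ± 0.09), which makes retinoic acid, and Foxc1 (0.46) rose. Neural plate and neural tube genes were higher in 5 of 8, or 4 in the labelled-number pairing (median 0.29, adjusted p = 0.000117, and adjusted p = 0.643 with an estimated correlation), with Gbx2 at 0.74 ± 0.10, Sox2 at 0.52 ± 0.09 and Nkx6-1 at 0.50 ± 0.09. Notochord and node genes were higher in 4 of 7, or 2 (median 0.16, adjusted p = 0.034, and adjusted p = 0.643 with an estimated correlation), led by Car3 (0.38) and Nodal (0.33). That call ended in 3 of 19 alternatives. Neural crest and surface ectoderm genes were higher in 7 of 10, or 3 (median 0.15, adjusted p = 0.00766, and adjusted p = 0.643 with an estimated correlation), with Krt5 at 0.46 and Krt14 at 0.43. That call also ended in 3, among them median centring, where the median of 0.23 lay below the 0.28 over all genes (adjusted p = 0.692).

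Retinoic acid genes were higher in 8 and lower in 2 of 13, or 3 and 1 in the labelled-number pairing (median 0.17, adjusted p = 0.0238, and adjusted p = 0.643 with an estimated correlation). Crabp2, a retinoic acid binding protein, rose by 0.74 ± 0.10, and Cyp26a1, which degrades retinoic acid, fell to a log2 ratio of -0.65 ± 0.10. Rarb rose (0.40). FGF genes were higher in 10 and lower in 1 of 15, or 3 and 1 (median 0.16, adjusted p = 0.017, and adjusted p = 0.699 with an estimated correlation), with Fgf15 at 0.59 ± 0.09, Fgf18 at 0.38, Fgf17 at 0.37 and the phosphatase gene Dusp4 at -0.62 ± 0.11. Wnt genes were higher in 15 and lower in 5 of 27, or 5 and 2 (median 0.13, adjusted p = 0.0441, and adjusted p = 0.827 with an estimated correlation). Nkd1 (0.57) and Notum (0.38) rose, and Rnf43 (-0.47) and Sfrp1 (-0.42, with its other probe at -0.082) fell. The calls of the Wnt, retinoic acid and FGF lists ended in 8, 6 and 2 of 19 alternatives. With 1 pair left out, the Wnt median ranged from 0.082 to 0.20 and the FGF median from 0.092 to 0.21. Germ cell genes were higher in 4 and lower in 1 of 8, or 3 and 0 (median 0.14, adjusted p = 0.0339, and adjusted p = 0.643 with an estimated correlation), with Alpl at 0.52 and Tfap2c at 0.45. That call ended in 10 of the 19.

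Of the Hox lists, only that of groups 10 to 13 passed. In paralogous groups 1 to 4, 3 of 12 were higher and 2 lower, or 3 and 0 in the labelled-number pairing, with Hoxb1 at 0.41 and Hoxb2 at 0.41 on 1 probe and -0.0011 on its other (median -0.04 and camera direction up, adjusted p = 0.446). In groups 5 to 9, 3 of 14 were higher and 4 lower, or 2 and 3 (adjusted p = 0.546). Hoxd9 (0.62 ± 0.09) and Hoxa5 (0.44) rose, and Hoxc6 (-0.52 ± 0.10) and Hoxa9 (-0.42) fell. In groups 10 to 13, 3 of 6 were lower and 0 higher, or 2 and 0 (median -0.17, adjusted p = 0.00671, and adjusted p = 0.682 with an estimated correlation), with Hoxd13 at -0.65 ± 0.10 and Hoxa11 at -0.44. That call ended in 3 of 19 alternatives.

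Hypoxia and glycolysis genes were lower in 13 and higher in 2 of 18, but lower in 3 and higher in 1 in the labelled-number pairing (median -0.26, adjusted p = 0.000537, and adjusted p = 0.643 with an estimated correlation). With median centring the median was 0.21 against 0.28 over all genes, and the call ended (adjusted p = 0.692), as it did in 3 of 19 alternatives in all. Bnip3 was at -0.47 and Ndrg1 at 0.58. Lists without a call, with counts of higher and lower genes in the exchange pairing, were Notch and segmentation clock (8 higher and 3 lower of 16, adjusted p = 0.161), axial progenitor and primitive streak (6 and 3 of 17, adjusted p = 0.507), gut endoderm (5 and 3 of 16, adjusted p = 0.75) and lateral plate and allantois mesoderm (4 and 8 of 19, adjusted p = 0.176). The same held for intermediate mesoderm (2 and 0 of 4, adjusted p = 0.146), cardiac mesoderm (3 and 0 of 7, adjusted p = 0.114) and cell cycle (2 and 7 of 22, adjusted p = 0.124). It also held for p53 pathway and apoptosis (3 and 5 of 15, adjusted p = 0.291), immediate early and stress genes (2 and 5 of 13, adjusted p = 0.124) and sex-linked genes (0 and 1 of 3, adjusted p = 0.82). In the labelled-number pairing, the higher and lower counts were 3 and 1 for Notch, 2 and 1 for axial progenitor, 1 and 2 for gut endoderm, and 2 and 4 for lateral plate. They were 1 and 0 for both intermediate and cardiac mesoderm, 0 and 1 for both cell cycle and p53, and 0 and 0 for both immediate early and sex-linked genes. Of the lists without a call, cell cycle gained one in 4 of the 19 alternatives, as lower in 3 and as higher in 1 with median centring (median 0.44, adjusted p = 0.0187). Immediate early genes gained one in 2, both as lower, and Notch, lateral plate and cardiac mesoderm in 1 each. Adjusted over the list alone, counts were the same except in Notch (10 higher), somite (10), neural plate (6), notochord (5), p53 (6 lower) and hypoxia (14 lower). The Cdx list passed as well (adjusted p = 9.39e-14, and adjusted p = 0.643 with an estimated correlation), a call that ended in 7 of 19 alternatives. The arrays were aligned after the ratios of these genes had been seen, so that pass is no separate support. Its members also went both ways, with Cdx4 at -2.48, Cdx2 at -0.54 and Cdx1 at 0.40. No list call held with an estimated correlation, where the smallest adjusted p = 0.643, an estimate that rests on 1 residual degree of freedom.

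**Figure D2:**
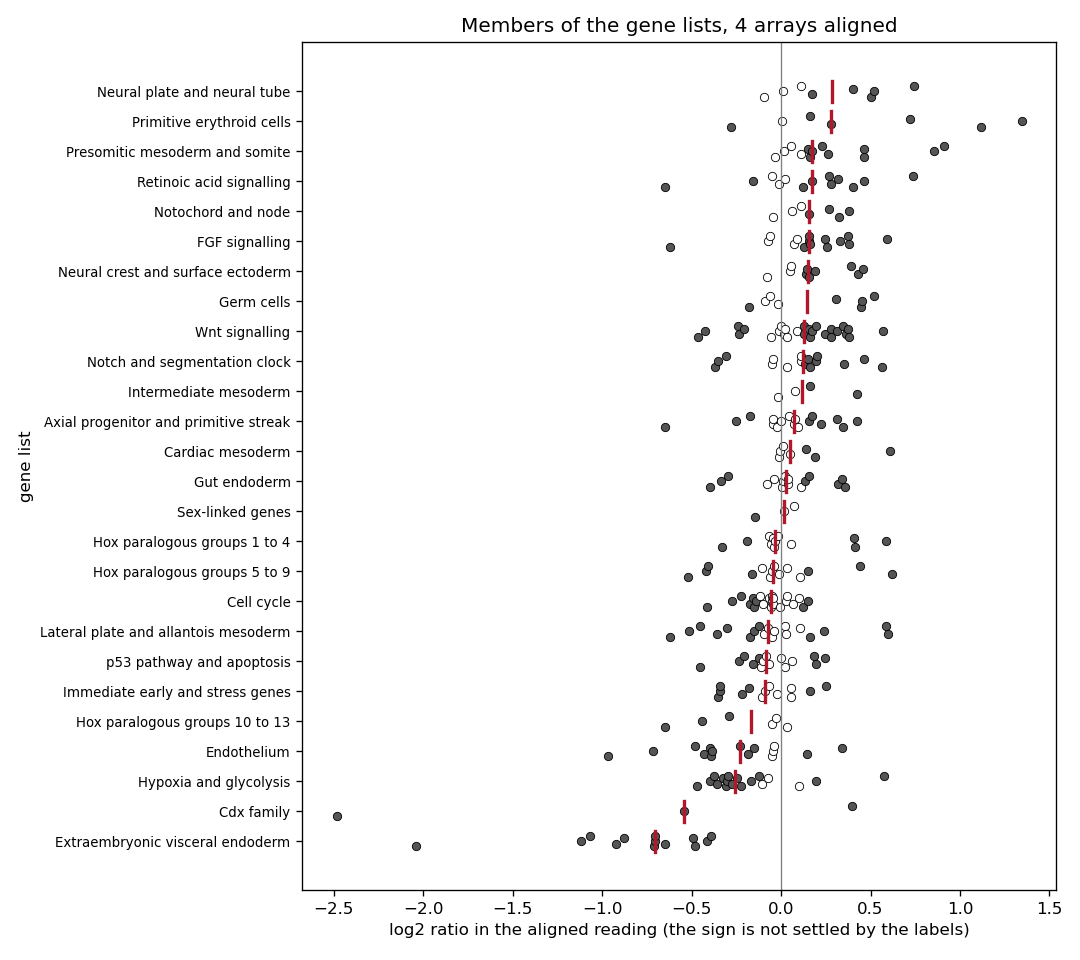
Aligned log2 ratios (horizontal axis) of the measured members of each fixed gene list (vertical axis), 1 point per gene as the mean of 4 arrays, filled where the gene passed in the exchange pairing, with a red bar at the list's median. Visceral endoderm lies lowest with a median of -0.71 and neural plate highest with 0.29, and every sign turns if the labels of the other 2 arrays are right.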

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

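All tests in this part were chosen after results had been seen. The second endoderm list was written after the ratios of 5 of its genes had been printed, and those 5 are left out of its test. Any gene that is also in a fixed list is left out as well.

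The aligned log2 ratios of 5 named genes and 1 background measure had 1 array far from the other 3. Chance alone marks about 1 in 20 groups, and 117 groups of 4 values were examined. Col26a1 was 1.05 on the array labelled replicate 2 dye swap against 1.25 to 1.28 on the others. Fam183b was 1.31 on the array labelled replicate 1 against 1.09 to 1.11, and Fgf15 was 0.50 there against 0.62 to 0.63. On the array labelled replicate 1 dye swap, Lhx1 was 0.41 against 0.43, Bnip3 was -0.28 against -0.54 to -0.52, and the median Cy5 background was 81.5 against 81 units.

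The spike-in control spots, which no comparison used, gave a signal. Their lowest median intensity over channels and arrays was 1648, against at most 105.6 for negative controls. All 10 spike-ins had a higher log2 Cy5 over Cy3 on the arrays labelled replicate 1 and its dye swap than on the other 2, by 0.36 on average (SD 0.13 over spike-ins). The median difference between 2 arrays of 1 labelled replicate was 0.02.

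The ratios ran against the labels on 2 of the 4 arrays. Dye bias as the cause is argued against, since arrays with the same labelled dyes correlated at -0.427 or lower. Exchanged dye columns are argued against as well, since spike-in ratios correlated at 0.997 or higher between any 2 arrays, provided the spike-in mixes followed the dyes. Labels exchanged between 2 arrays and wrong dyes with right replicate numbers cannot be told apart: turning the arrays gives a lowest correlation of 0.378 in both cases, with a sign set by the turning itself. Which labels are wrong, and so the sign of every aligned ratio, stays open by the labels alone. With the opposite sign, Cdx4 would be 5.60-fold higher in Cdx4-/- tissue and Cdx2 1.46-fold higher in Cdx2+/- tissue. These values of the targeted genes argue against the opposite sign, as far as their transcripts are lost in the mutant.

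All 13 visceral endoderm markers were lower in the aligned ratios. Dye bias is argued against, since on the array closest to 0 their median was still -0.537. The 13 genes of a second list not printed earlier had a median of -0.387, with 10 lower and 1 higher (Maf, 0.26). A different share of visceral endoderm in the tissue may underlie the pattern. The second list cannot tell this from lower expression of these genes within the same share, since both would lower it. Whether such a share comes from dissection or from genotype cannot be told apart, because the labels describe pools of each genotype and not single embryos.

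Defensin genes were among the largest increases. Of the 8 tested, 100% were higher, but 6 of them prompted the question. One signal read by probes of near-identical genes and a joint increase of several genes cannot be told apart by this. For the 4 defensin genes with a position, DNA of another strain around the targeted genes is argued against, with 0 of them within 10 Mb of Cdx2 or Cdx4. Strain differences elsewhere in the genome were not tested.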

How the results depend on the processing

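All alternatives of the aligned fit, and the aligned fit itself, were chosen after the data were seen, and those of the fit as labelled were planned, except its fits of the 2 arrays of 1 labelled replicate. The planned fit of 4 arrays with the labelled replicate as a random block (duplicateCorrelation) could not be fitted, since it gave no correlation estimate, and was not run. Leaving out 1 replicate leaves 1 averaged value, which was not tested. Tests with the 2 arrays that remain as separate values are given below by their array numbers or labelled replicate, and their spread is that between arrays. The pairing of the aligned arrays was tried in 3 ways: 6000 genes were called in the exchange pairing, 7932 in the third and 1016 in the labelled-number pairing. All 1016 were among the 6000. Of the named genes, 86 were called in all 3 pairings, including the 24 largest changes. Below, each count that moved over 1.5 times, each called list that lost its call and each sign change of a called result is given. Of the 110 named genes, all called in the aligned fit and 0 in the fit as labelled, those that lost the call with their sign kept numbered 1 with eBayes with trend and robust, 1 with mean of all probes of a gene, 98 with median centring in place of loess (and 12 more with a change of sign), 12 with only arrays 1 and 2 (and 1 more with a change of sign), 51 with only arrays 1 and 3, 77 with only arrays 2 and 4, 3 with only arrays 3 and 4, 43 with only the 2 arrays whose labels go with Cdx4, 24 with pairs 1 with 2 and 3 with 4, 2 with scanner processed signals and median centred and 2 with series matrix values. Where the fit as labelled called 0 genes in limma, 0 to 682 were at an unadjusted p under 0.05. With median centring in place of loess, the aligned fit called 0 genes, 29 were at an unadjusted p under 0.05 and the median standard error was 0.49. There Cy5 over Cy3 drifted with brightness by a different amount on each array, with medians of 0.16, 1.86, 0.52 and -0.53 in the brightest 1 of 6 parts of the tested probes on arrays 1 to 4, and the median aligned ratio of all tested probes was 0.23. Subsets of 2 aligned arrays are named by array number, since the dye of the mutant is open: arrays 1 and 3, and arrays 2 and 4, have the same dyes by the labels, and arrays 1 and 2, and arrays 3 and 4, when aligned. Causes were not tested. Between 50.6% and 64.9% of spots per channel were well above background, which limits what could be tested.

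In the fit as labelled, the 14 genes called became 0 under these settings: no background correction, scanner processed signals with median centring, median centring in place of loess, no filter on dim probes, series matrix values, only arrays with the mutant in Cy5, only arrays with the mutant in Cy3, 4 arrays as separate values with a dye term, only the 2 arrays of labelled replicate 1, only the 2 arrays of labelled replicate 2, scanner p under 0.01 on all 4 arrays in 1 direction and adjusted p under 0.05 and 1.5-fold or more. The count was 9 with eBayes with trend and robust. The call of the p53 list, the 1 list past the threshold as labelled, ended in 12 of 16 alternatives, all but these: loess then Aquantile, no filter on dim probes, well above background in both channels and eBayes with trend and robust. With median centring of each array, where p53 had adjusted p = 0.142, the list Cell cycle gained a call as lower (median -0.17, adjusted p = 0.00287), and in the rest of the 12 no list passed. The median of the p53 list as labelled was 0.00541 with series matrix values. Setting "no background correction" gave 4497 genes called lower and 14 genes 2-fold lower in both pairs. With no background correction, list medians that lost the call were -0.58 for Cdx family, 0.097 for Wnt signalling and 0.20 for Germ cells. Setting "scanner processed signals with median centring" gave 9 gene lists past the threshold, 74 genes 2-fold higher in both pairs and 164 genes 2-fold lower in both pairs. With scanner processed signals with median centring, list medians that lost the call were -0.60 for Cdx family, -0.39 for Hox paralogous groups 10 to 13, 0.14 for Wnt signalling, 0.16 for Retinoic acid signalling and 0.22 for Germ cells. Setting "median centring in place of loess" gave 0 genes called higher, 0 genes called lower and 2 genes 2-fold lower in both pairs. With median centring, list medians that lost the call were 0.48 for Retinoic acid signalling, 0.45 for Notochord and node, 0.45 for Germ cells and 0.23 for Neural crest and surface ectoderm. Among the genes that lost the call with median centring were the targeted genes Cdx2 (-0.11) and Cdx4 (-2.24). With median centring, the median over all genes tested was 0.28, and list medians that crossed 0 on that shifted scale were 0.033 for Endothelium, which kept its call as lower than other genes (adjusted p = 0.00365), 0.44 for Cell cycle, which gained a call as higher than other genes (adjusted p = 0.0187), 0.21 for Hypoxia and glycolysis, whose call ended (adjusted p = 0.692) and 0.025 for Immediate early and stress genes, which gained a call as lower than other genes (adjusted p = 0.042). Genes that changed sign on that scale, all losing the call, were Hoxd4 (0.041), Hey1 (0.10), Cpm (0.037), Hba-a1 (0.018), Mki67 (0.14), Top2a (0.16), Aurka (0.36), Mcm4 (0.43), Zmat3 (0.069), Sesn2 (0.20), Junb (0.025) and Ddx3y (0.11). Setting "series matrix values" gave 76 genes 2-fold higher in both pairs and 153 genes 2-fold lower in both pairs. With series matrix values, list medians that lost the call were -0.59 for Cdx family, 0.15 for Wnt signalling, 0.17 for Retinoic acid signalling and 0.23 for Germ cells. With 4 arrays as separate values with a dye term, list medians that lost the call were -0.54 for Cdx family and 0.14 for Germ cells. Setting "estimated correlation" gave 0 gene lists past the threshold. With estimated correlation, list medians that lost the call were -0.54 for Cdx family, -0.17 for Hox paralogous groups 10 to 13, 0.13 for Wnt signalling, 0.16 for FGF signalling, 0.17 for Retinoic acid signalling, 0.17 for Presomitic mesoderm and somite, 0.29 for Neural plate and neural tube, 0.16 for Notochord and node, -0.23 for Endothelium, 0.28 for Primitive erythroid cells, -0.71 for Extraembryonic visceral endoderm, 0.14 for Germ cells, 0.15 for Neural crest and surface ectoderm and -0.26 for Hypoxia and glycolysis. Setting "scanner p under 0.01 on all 4 arrays in 1 direction" gave 173 genes called higher and 299 genes called lower. Setting "adjusted p under 0.05 and 1.5-fold or more" gave 84 genes called higher and 107 genes called lower. With the filter well above background in both channels, list medians that lost the call were 0.14 for Wnt signalling. Setting "only arrays 1 and 2" gave 1813 genes called lower and 8 gene lists past the threshold. With only arrays 1 and 2, list medians that lost the call were 0.15 for Wnt signalling, 0.15 for FGF signalling, 0.28 for Retinoic acid signalling, 0.18 for Notochord and node, 0.15 for Neural crest and surface ectoderm and -0.12 for Hypoxia and glycolysis. The gene that changed sign with only arrays 1 and 2, losing the call, was Junb (0.10). Setting "only arrays 3 and 4" gave 9 gene lists past the threshold and 16 genes 2-fold lower on both arrays. With only arrays 3 and 4, list medians that lost the call were -0.45 for Cdx family, -0.18 for Hox paralogous groups 10 to 13, 0.10 for Wnt signalling, 0.17 for Retinoic acid signalling and 0.10 for Germ cells. Setting "only arrays 1 and 3" gave 162 genes called higher and 295 genes called lower. With only arrays 1 and 3, list medians that lost the call were 0.082 for Wnt signalling and 0.16 for Germ cells. Setting "only arrays 2 and 4" gave 65 genes called higher and 57 genes called lower. With only arrays 2 and 4, list medians that lost the call were 0.13 for Germ cells. Among the genes that lost the call with only arrays 2 and 4 was the targeted gene Cdx2 (-0.48). Setting "only the 2 arrays whose labels go with Cdx4" gave 223 genes called higher and 349 genes called lower. With pairs 1 with 4 and 2 with 3, list medians that lost the call were -0.54 for Cdx family and 0.14 for Germ cells. Setting "pairs 1 with 2 and 3 with 4" gave 436 genes called higher and 580 genes called lower. Setting "the 2 other arrays as labelled" gave 256 genes called higher and 237 genes called lower. In single exchange pairs, 8 and 16 genes were 2-fold or more lower, counts of 1 pair that cannot be set against the 7 in both. With 1 exchange pair left out, the median log2 ratio of the list Hypoxia and glycolysis ranged from -0.25 to -0.23. With 1 exchange pair left out, the median log2 ratio of the list Presomitic mesoderm and somite ranged from 0.18 to 0.21. Of the 19 alternatives with a list test, the call of each called list ended in the following number: 7 for Cdx family, 3 for Hox paralogous groups 10 to 13, 8 for Wnt signalling, 2 for FGF signalling, 6 for Retinoic acid signalling, 1 for Presomitic mesoderm and somite, 1 for Neural plate and neural tube, 3 for Notochord and node, 1 for Endothelium, 1 for Primitive erythroid cells, 1 for Extraembryonic visceral endoderm, 10 for Germ cells, 3 for Neural crest and surface ectoderm and 3 for Hypoxia and glycolysis. No called list was called the other way. Lists without a call gained one as follows: Notch and segmentation clock (adjusted p = 0.0493) and Cardiac mesoderm (adjusted p = 0.0365) as higher with no filter on dim probes, Lateral plate and allantois mesoderm (adjusted p = 0.0451), Cell cycle (adjusted p = 0.0137) and Immediate early and stress genes (adjusted p = 0.0241) as lower with no filter on dim probes, Cell cycle (adjusted p = 0.0472) as lower with 4 arrays as separate values with a dye term and Cell cycle (adjusted p = 0.0174) as lower with only arrays 2 and 4. With 1 exchange pair left out, list medians that moved over 1.5 times ranged from -0.046 to -0.012 for Hox paralogous groups 1 to 4, from -0.071 to -0.018 for Hox paralogous groups 5 to 9, from 0.082 to 0.20 for Wnt signalling, from 0.092 to 0.21 for FGF signalling, from 0.075 to 0.16 for Intermediate mesoderm, from -0.15 to -0.034 for Immediate early and stress genes and from -0.046 to 0.037 for Sex-linked genes.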

Other observations

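The lists in this part were chosen after the data were seen, and all signs are those of the aligned ratios, which turn with the labels of the other 2 arrays. Adjusted p-values here are those of the exchange pairing. In the imprinted Dlk1-Dio3 cluster, 3 of 5 measured genes were lower and 0 higher. Rian was at -2.47 on its brightest probe but at -0.0014 (adjusted p = 0.987) on its other probe, Meg3 at -0.66 and Dio3 at -0.44, while Dlk1 (0.07, adjusted p = 0.333) and Mirg (0.07, adjusted p = 0.341) did not pass. The list was picked because Rian and Meg3 had been seen, so it is not independent evidence. Of 19 other imprinted genes, 10 were lower and 3 higher (median -0.14). Plagl1 (-0.58), Igf2r (-0.54), Cdkn1c (-0.47) and H19 (-0.40) were lowest, Nnat (0.42) was highest, and Igf2 was at -0.04 (adjusted p = 0.624).

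Genes near the targeted loci did not stand apart in size of change. Within 10 Mb of Cdx2 or Cdx4, 3 of 241 tested genes (1.24%) were called and changed at least 1.5-fold, against 181 of 14519 elsewhere (1.25%, Fisher's exact test, two-sided p = 1).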
